A study of Mus musculus with 14 samples.

How the data were processed

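Total RNA from HL-1 cells, a mouse cardiac muscle cell line, was labelled with biotin and hybridised to Affymetrix arrays after transfection of siRNA at 10 nM with a lipid reagent, per the labels' protocols. There were 14 arrays in 3 groups, named as in the labels: siScramble (n = 6), siAirn-001.1 (n = 4) and siAirn-001.2 (n = 4). The labels call the arrays of a group biological replicates. Whether each came from a separate culture, on which day, and how long after transfection the RNA was taken is not given in the sources used here, so p-values measure only the spread between these arrays. What distinguishes siAirn-001.1 from siAirn-001.2 is not given either, and they are treated as 2 reagents. Each array carried 1 sample and 1 label.

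The authors deposited log2 expression values for every array. RMA, which corrects the background, equalises the distributions of the arrays and summarises the probes of each transcript cluster on the log2 scale, and limma are the tools named in the submitters' processing notes, without versions, roles or order. The array model, the genome build and the annotation are not given in the sources used here, and no coordinates are printed. RMA forces the arrays to near-equal distributions, so a change shared by most genes would not be visible, and it damps large differences between dim probes. The deposited table also holds the authors' log2 difference, p-value and adjusted p-value for all siAirn arrays against siScramble, per the file headers. That difference equals the mean of the 8 siAirn arrays minus the mean of the 6 siScramble arrays to within 0.0005. A second deposited table holds the same log2 values rounded to 2 decimals and gave no further information. All per-sample columns were matched to samples by name.

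The table has 20193 genes with 1 row per symbol, and no gene has a second row. Gene symbols are those of the deposited table. In a table of current mouse genes (assembly GRCm38.p6, used for names only), 17433 symbols were found as current names, 2024 as older names, and 736 were not found.

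The deposited log2 values were used without further normalisation or filtering. One linear model with 3 group means was fitted to all 14 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 11 residual and 5.31 prior degrees of freedom). Each test was two-sided, with Benjamini-Hochberg adjustment over the 20193 genes of a contrast and a threshold of 0.05 on the adjusted p. The contrasts tested were siAirn-001.1 minus siScramble, siAirn-001.2 minus siScramble, the mean of both siAirn groups minus siScramble, and siAirn-001.2 minus siAirn-001.1. Adjusted p-values without another name are from this limma fit, and an error after a log2 change is its standard error (SE) in the fit. The Airn level was in addition tested with an exact two-sided permutation of its array values.

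Gene lists, 32 in all, were written from textbook knowledge before the data were examined, as were the groups, the tests, the rule for naming genes and most of the other settings. Each list was tested in each contrast with limma's camera, which compares the list with all other genes at a preset correlation of 0.01 between members. Adjustment was over the 32 lists of a contrast, and lists needed at least 5 measured genes. Camera with a correlation estimated from the data, fry (which asks whether a list's genes move, on balance, one way) and, added after the data were seen, an exact two-sided permutation of each array's mean over the list were run as alternatives.

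The genes named are Airn, Igf2r, Slc22a2, Slc22a3 and Igf2bp2; the 10 largest rises and 10 largest falls past the threshold in the mean contrast whose 8 siAirn values all lay on the same side of the siScramble mean; the 5 largest each way for each reagent under the same condition on its 4 arrays; the 5 largest each way between the reagents whose arrays did not overlap; and the 2 largest called members of each list in the mean contrast. Symbols that begin with Gm and a digit, LOC, Mir, Snor, Olfr or Vmn or end in Rik, and controls from other species, were passed over. List members named beyond this rule were chosen after their values were seen. Some genes that the rule selects are not reported here.

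Because both reagents were set against the same 6 siScramble arrays, the overlap and the correlation of their changes were also computed after reassigning residuals to arrays 100 times, which leaves no effect, and with the controls split 3 against 3 in all 20 ways. Where the design allows, each count was compared with up to 100 other splits of the same arrays into groups of the same sizes. Array data carry no read depth; the number of arrays limits the precision, and the median SE of a log2 change was 0.0876 for a single reagent and 0.0733 for the mean of both. The fit was tested on simulated data with the real genes' means and spreads. These values were drawn independently for each gene and array, without the correlations of the real data. The false calls therefore hold for the simulation only. Of 100 genes changed 1.5-fold and 100 changed 2-fold among 20193, it called 85 and 100 in the siAirn-001.1 contrast, with 7 false calls. The same counts were 86 and 96 in the siAirn-001.2 contrast, with 10 false calls, and 94 and 98 in the mean contrast, with 10 false calls.

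Alternatives were the replicate number as a block, fits on only the groups compared, an intensity trend with a robust prior, array weights, repeated quantile normalisation, centring on the array median, leaving out the lowest 1/3 of genes by mean level, leaving out each array in turn, a 1.5-fold minimum and an adjusted p under 0.01. The replicate numbers paired the arrays of siAirn-001.1 with those of siAirn-001.2: deviations from the group means correlated across genes at 0.318 to 0.534 in all 4 same-numbered pairs. This pairing comes from the data, not from the labels. Added after the data were seen were the SD of each array as a covariate, leaving out siScramble arrays 5 and 6, consecutive replicate numbers as a block, and the permutation of list means without Airn in its locus list.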

Results

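Gene expression was measured on Affymetrix arrays in HL-1 cells, a mouse cell line of atrial heart muscle that keeps many features of cardiomyocytes in culture. The cells had received either a scrambled control siRNA (siScramble, 6 arrays) or 1 of 2 reagents named siAirn-001.1 and siAirn-001.2 (4 arrays each), all at 10 nM. Airn is a long non-coding RNA made from the paternal chromosome, antisense to Igf2r, and its transcription silences neighbouring genes of that imprinted locus. The comparisons ask how the transcriptome of these cells differed when Airn was targeted, with each reagent, with both on average, and between the reagents. Array medians lay between 7.45 and 7.55 on the log2 scale and their SDs between 2.09 and 2.19. Pairs of arrays correlated at 0.988 to 0.998 across genes, and no 2 arrays held identical values. The number of arrays limits the precision of every value.

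Airn itself (transcript cluster 10441787) was measured at 11.98 ± 0.13 (SD, n = 6) with siScramble, 11.39 ± 0.53 (SD, n = 4) with siAirn-001.1 and 11.29 ± 0.60 (SD, n = 4) with siAirn-001.2, a level above 96.5% of genes. Its log2 change was -0.59 ± 0.23 with siAirn-001.1 and -0.69 ± 0.23 with siAirn-001.2, and their mean was -0.64 ± 0.19. In the exact permutation test of its array values, p was 0.019, 0.0143 and 0.0167 for these contrasts. After adjustment over all genes none passed in limma, with adjusted p-values of 0.168, 0.193 and 0.0754, and the reagents did not differ detectably (log2 difference -0.11, exact permutation p = 0.629). With the replicate number as a block, which did not pair the siScramble arrays with the others, Airn passed in all 3 contrasts (log2 change -0.56, -0.66 and -0.61, adjusted p = 0.0405, 0.0418 and 0.0169), and with array weights for siAirn-001.2 and the mean (adjusted p = 0.0208 and 0.0152). The arrays within each siAirn group were far apart. Relative to the siScramble mean, siAirn-001.1 arrays 1 to 4 held 93.5%, 89.2%, 48.4% and 48.3% of the Airn signal, and siAirn-001.2 arrays 1 to 4 held 96.2%, 80.5%, 41.4% and 45.5%. The siScramble arrays spanned 86.8% to 112.7%, so Airn lay inside the siScramble range in 3 arrays labelled siAirn. Groups are therefore named by their labels, and every direction given for them includes those 3 arrays. Leaving out siAirn-001.1 array 1 took the mean change to -0.72 (adjusted p = 0.0484), and leaving out siAirn-001.2 array 1 took it to -0.75 (adjusted p = 0.0315). Which part of Airn the array measures, and which part the siRNAs target, is not given in the sources used here.

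**Figure D1:**
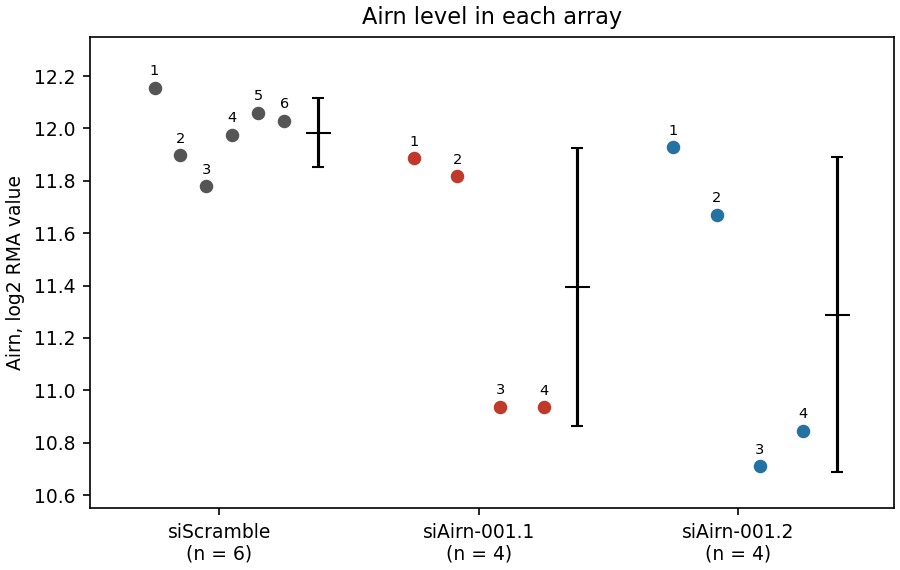
Airn level in each array as log2 RMA value, with points numbered by replicate and bars giving the mean ± SD of each group (n = 6, 4 and 4). Arrays 3 and 4 of both siAirn groups lie below 11, and 3 siAirn arrays lie inside the siScramble range.

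The genes around Airn were not called in any contrast of the fit used here. Igf2r, the receptor that clears IGF2 and the target of silencing by Airn, was at 6.91 ± 0.06 (SD, n = 6) with siScramble, 6.78 ± 0.10 (n = 4) with siAirn-001.1 and 6.85 ± 0.03 (n = 4) with siAirn-001.2, a mean log2 change of -0.09 (adjusted p = 0.439). The organic cation transporter genes Slc22a2 and Slc22a3 had mean changes of -0.09 (adjusted p = 0.748) and -0.03 (adjusted p = 0.943). Over all arrays Slc22a2 lay between 6.28 and 6.78 and Slc22a3 between 6.40 and 6.77. Like Igf2r they lay below the siScramble median of all genes, 7.49, so a change in them may have been damped. Igf2bp2, which encodes an mRNA-binding protein, had a mean change of -0.21 (adjusted p = 0.289), and passed with array weights (-0.31, adjusted p = 0.0363) and with consecutive replicate numbers as a block (-0.32, adjusted p = 0.0355). The list of 12 measured genes of the Airn locus, of which Airn and Sod2 (0.15) had an unadjusted p under 0.05 in limma, was not called in the mean contrast by camera (adjusted p = 0.559), nor were imprinted genes elsewhere (adjusted p = 0.653). Among 18 IGF2BP family and target genes, Myc, a growth-promoting transcription factor, was lower by a log2 change of -0.58 (adjusted p = 0.0385) and the cyclin gene Ccnd1 by -0.45 (adjusted p = 0.0272). With 1 array left out, Myc was lost in 7 of 14 fits (adjusted p up to 0.113) and Ccnd1 in 6 (up to 0.0765). Both were lost in the fit of the 8 siAirn arrays as 1 group. In siAirn-001.2 arrays 3 and 4, where Airn was low, both genes lay inside the siScramble range (Myc 9.07 and 8.92, Ccnd1 8.64 and 8.59). These 2 members were also the ones past the threshold adjusted over the list alone, and the list as a whole was not called for the mean by camera (adjusted p = 0.489). With siAirn-001.1, camera called neither the Airn locus list nor this one (adjusted p = 0.672 and 0.178), while the exact permutation of array means called both lower (adjusted p = 0.0218 and 0.0416). The call of the locus list rested on Airn itself: without Airn the other 11 genes had a mean of -0.02 (adjusted p = 0.762).

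Averaged over both reagents, the largest falls included genes of an integrin and of matrix proteins, and the largest rises included genes of a potassium channel subunit and of mitochondrial proteins. Itga8, an integrin subunit, fell by 1.06 ± 0.11 on the log2 scale (adjusted p = 0.000122), and the small leucine-rich proteoglycan genes Prelp and Fmod fell by 0.92 ± 0.08 and 0.85 ± 0.13 (adjusted p = 2.53e-05 and 0.00126). Matn3, a cartilage matrix protein gene, changed by -0.84, and Adra2b, an alpha-2 adrenergic receptor gene, by -0.79. Itih4, of the inter-alpha-trypsin inhibitor family, rose by 1.15 ± 0.21 (adjusted p = 0.00585), and Kcnj3, a subunit of the atrial acetylcholine-activated potassium channel, by 0.81 ± 0.10 (adjusted p = 0.000429). The mitochondrial genes Shmt2, an enzyme of serine and folate metabolism, and Mrpl21, a ribosomal protein, rose by 0.71 ± 0.08 and 0.72 ± 0.08. By the rule that chose them, each of these genes lay on one side of the siScramble mean in all 8 siAirn arrays.

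The remaining named rises in this contrast were Usp18, a protease that removes ISG15 (0.94 ± 0.22), the stress-induced Nupr1 (0.90 ± 0.18), Shisa6 (0.80 ± 0.09), the interferon-induced GTPase gene Irgm1 (0.79 ± 0.17), Cideb (0.74 ± 0.18) and the proton pump subunit gene Atp6v0e2 (0.73 ± 0.08). The remaining named falls were the ATP-gated channel gene P2rx1 (-0.93 ± 0.25), Them5 (-0.87 ± 0.14), the metalloprotease gene Adamts8 (-0.78), the calcium sensor gene Ncs1 (-0.75) and the phosphatase gene Ptprj (-0.70). In all, 833 genes passed the threshold, 435 higher and 398 lower, and 71 of them changed at least 1.5-fold. The balance depended on the setting: it was 460 higher and 267 lower with arrays centred on their median, 714 and 836 with the replicate block, 872 and 1055 with array weights, and 441 and 540 without siScramble array 6. Of the 20 named genes, 14 passed whichever array was left out. P2rx1 was lost in 10 of the 14 fits (adjusted p up to 0.128), Cideb in 8 (up to 0.09), and Usp18 without any of siScramble arrays 1 to 4 (up to 0.061). Irgm1 and Adamts8 were lost without siScramble array 4 (0.05 and 0.0589) and Ptprj without siScramble array 2 (0.0557). The count fell to 468, 404 and 378 without siScramble arrays 1, 2 and 4, and a fit of the 8 siAirn arrays as 1 group gave 548. The authors' deposited table lists 292 genes with an adjusted p under 0.05 for this contrast, and all 292 are among the 833, in the same direction.

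**Figure D2:**
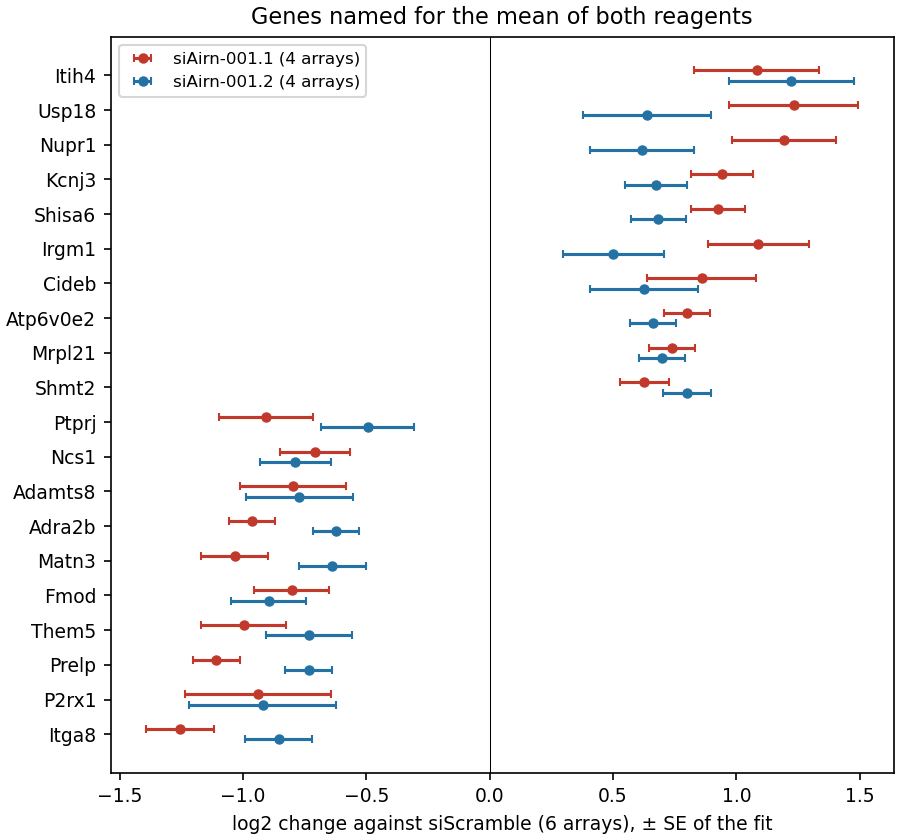
Log2 change against siScramble (n = 6) of the 20 genes named for the mean of both reagents, for siAirn-001.1 and siAirn-001.2 (n = 4 each), with bars giving the SE of the fit. The 10 largest rises and 10 largest falls are shown among called genes with all 8 siAirn values on one side of the siScramble mean, without the symbols passed over. Of these Itih4 and Itga8 have the largest mean rise and fall, 1.15 and -1.06.

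Among the gene lists, genes of oxidative phosphorylation were higher on average over both reagents: 14 of 67 rose, or 22 adjusted over the list alone. The median log2 change of this list was 0.14, with 64 members above 0 (camera adjusted p = 2.89e-17, and adjusted p = 0.269 with an estimated correlation). Its means in arrays 1 to 4 were 0.28, 0.21, 0.06 and 0.13 with siAirn-001.1 and 0.19, 0.21, 0.04 and 0.18 with siAirn-001.2. The siScramble means were -0.06 to 0.08, so array 3 of each reagent lay inside their range. Its largest rises were in the muscle isoforms of cytochrome oxidase subunits, Cox6a2 (0.88, adjusted p = 0.0194) and Cox7a1 (0.60, adjusted p = 0.0132). With 1 array left out, Cox6a2 was lost in 3 of 14 fits (adjusted p up to 0.0587) and Cox7a1 in none. In siAirn-001.2 arrays 3 and 4 Cox6a2 (9.69 and 9.85) lay inside the siScramble range (9.47 to 10.03). In fatty acid oxidation, 4 of 31 genes rose, Cpt2 (0.22), Pdk4 (0.44), Ucp2 (0.40) and Ppara (0.40), and 8 did adjusted over the list alone. That list had a median of 0.11 (adjusted p = 3.95e-07, and adjusted p = 0.269 with an estimated correlation). Interferon response genes had a median of 0.19, and 9 of 48 rose, among them Usp18 and Irgm1, or 19 adjusted over the list alone (adjusted p = 9.07e-12, and adjusted p = 0.269 with an estimated correlation). List members named beyond the stated rule, here and in the other contrasts, were chosen after their values were seen.

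Targets of p53, ribosome biogenesis genes and extracellular matrix genes were lower on average. Of 31 p53 targets, 5 fell, namely Plk2 (-0.67), Polk (-0.52), Aen (-0.41), Trp53inp1 (-0.38) and Ei24 (-0.28). Adjusted over the list alone, 11 were lower and 2 higher, and the list's median was -0.24 (adjusted p = 4.78e-06, and adjusted p = 0.484 with an estimated correlation). With siAirn-001.2 camera did not call this list (adjusted p = 0.181). Its means there, -0.11, -0.15, -0.01 and -0.01 in arrays 1 to 4, lay inside the siScramble range (-0.17 to 0.20). Plk2 in siAirn-001.2 arrays 3 and 4 (9.38 and 9.42) did so too (9.06 to 9.42). Its call was lost without siScramble array 2 or 4 (adjusted p up to 0.0586). Ribosome biogenesis genes had a median of -0.26 with 2 of 46 above 0, and 2 of them fell, Wdr12 (-0.38) and Nop14 (-0.33), or 16 adjusted over the list alone (adjusted p = 5.34e-14, and adjusted p = 0.528 with an estimated correlation). The list means were -0.46 and -0.55 in siAirn-001.1 arrays 1 and 2, and -0.35 and -0.39 in siAirn-001.2 arrays 1 and 2. In arrays 3 and 4, where Airn was lowest, they were -0.16 and -0.02, and -0.04 and -0.01. Those 4 arrays lay inside the siScramble range (-0.23 to 0.13). Extracellular matrix genes had a median of -0.08, and Fbn2, which encodes a fibrillin, was the 1 of 43 that fell (-0.45, adjusted p = 0.00269), as it was adjusted over the list alone. The adjusted p of this list was 0.0227, 0.824 with an estimated correlation, 0.0919 without siScramble array 4 and 0.136 without siAirn-001.1 array 1. The siScramble arrays 5 and 6 stood apart from the other 4 in some of these lists, with list means of -0.13 and -0.23 for ribosome biogenesis and 0.20 and 0.14 for p53 targets, relative to the siScramble mean. No list was called for the mean by camera with an estimated correlation (3 at unadjusted p under 0.05) or by exact permutation of array means (7 at unadjusted p under 0.05), and fry called 3.

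**Figure D3:**
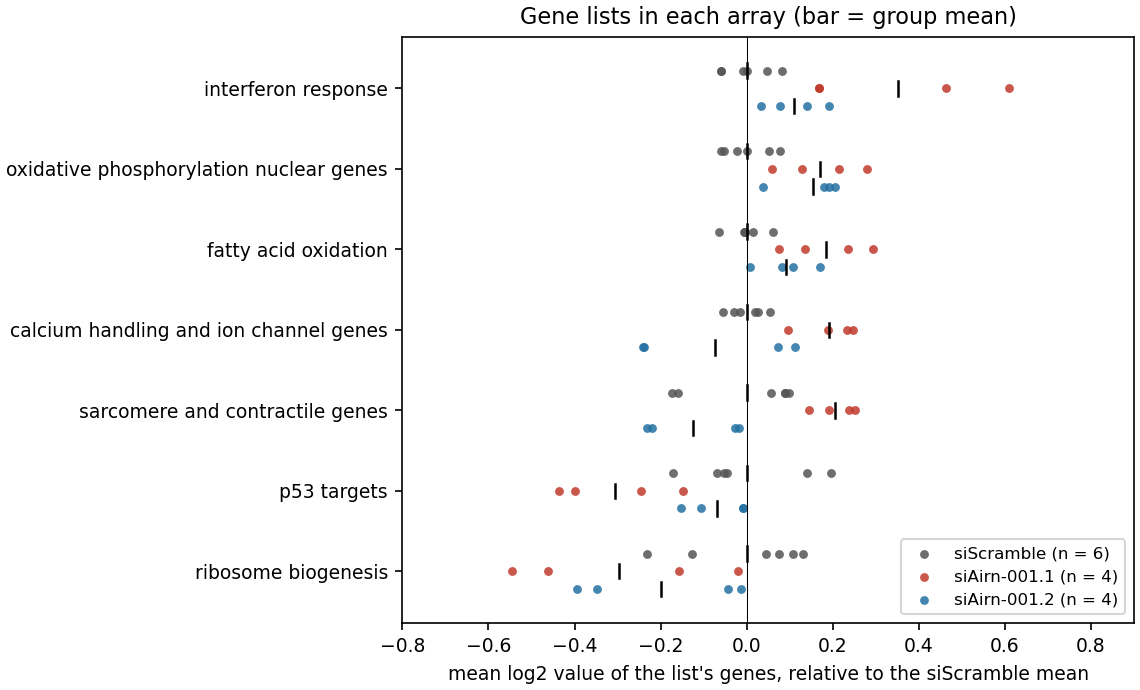
Mean log2 value of the genes of 7 lists in each array, relative to the siScramble mean, with group means as bars (n = 6, 4 and 4). Interferon response means of the siAirn-001.1 arrays lie between 0.17 and 0.61, and sarcomere means of the siAirn-001.2 arrays between -0.23 and -0.02.

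In arrays labelled siAirn-001.1, of which 2 had Airn inside the siScramble range, the largest changes included rises of a transporter and metabolic enzymes and falls of growth factors. Slc38a3, a glutamine transporter gene, rose by 1.43 ± 0.26 (adjusted p = 0.00402), Hsd3b1, a steroid-converting enzyme gene, by 1.30 ± 0.17 (adjusted p = 0.000341), and Gfpt2, of the hexosamine pathway, by 1.29 ± 0.17 (adjusted p = 0.000341). Usp18 and Nupr1 rose by 1.23 ± 0.26 and 1.19 ± 0.21. The growth factor genes Tgfb2 and Bmp4 fell by 1.34 ± 0.26 (adjusted p = 0.00632) and 1.30 ± 0.14 (adjusted p = 6.62e-05). The kinase gene Pak3 fell by 1.30 ± 0.19, Itga8 by 1.25 ± 0.14, and Papss2, which makes the sulfate donor of the cell, by 1.12 ± 0.25. By the rule that chose them, all 4 arrays lay on the same side of the siScramble mean for each. All 10 genes passed whichever array was left out. In total 1203 genes passed, 693 higher and 510 lower, 241 of them at least 1.5-fold. The split was 794 and 358 with arrays centred on their median, 966 and 879 with the replicate block and 987 and 919 with array weights, and the count was 797 and 770 without siScramble arrays 2 and 4.

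Of the gene lists, 6 were higher with siAirn-001.1. Sarcomere genes had a median of 0.24: 7 of 28 rose, including Ldb3 (0.65), and Myl2 fell (-0.54), with 9 and 2 adjusted over the list alone (adjusted p = 0.000137, and adjusted p = 0.45 with an estimated correlation). The sarcomere call was lost with the replicate number as a block (adjusted p = 0.0622) and without siScramble arrays 5 and 6 (adjusted p = 0.0577), whose list means were -0.17 and -0.16. Calcium handling and ion channel genes had a median of 0.11: 7 of 34 rose, including Kcnj3 (0.94) and the calcium-binding S100a1 (0.77), and Casq1 fell (-0.35), with 8 and 1 adjusted over the list alone (adjusted p = 8.04e-05, and adjusted p = 0.45 with an estimated correlation). Of 48 interferon genes 20 rose, or 27 adjusted over the list alone, with a median of 0.32 (adjusted p = 5.11e-14, and adjusted p = 0.254 with an estimated correlation). The interferon list means of siAirn-001.1 arrays 1 to 4 were 0.17, 0.17, 0.46 and 0.61. Oxidative phosphorylation, with 11 of 67 genes higher and 15 adjusted over the list alone, had a median of 0.14 (adjusted p = 7.77e-12). Fatty acid oxidation, with 4 of 31 higher and 8 adjusted over the list alone, had a median of 0.16 (adjusted p = 4.1e-07). With an estimated correlation the adjusted p was 0.254 for both. Lipogenesis had a median of 0.15, with Acacb (0.42), Dgat2 (0.38) and Acss2 (0.28) higher of 22, the same number as adjusted over the list alone (adjusted p = 0.00459, and adjusted p = 0.45 with an estimated correlation).

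The lower lists with siAirn-001.1 were p53 targets, ribosome biogenesis and histone genes. Of 31 p53 targets 9 fell, the largest change being that of Plk2, a stress-induced kinase gene (-1.02), and 21 fell adjusted over the list alone, with a median of -0.37 (adjusted p = 4.4e-09, and adjusted p = 0.254 with an estimated correlation). Of 46 ribosome biogenesis genes, Utp20 (-0.65), Nop58 (-0.59), Wdr12 (-0.53), Dkc1 (-0.43) and Nop14 (-0.41) fell, 17 adjusted over the list alone, with a median of -0.30 (adjusted p = 2.67e-12, and adjusted p = 0.45 with an estimated correlation). The list means of ribosome biogenesis in siAirn-001.1 arrays 1 to 4 were -0.46, -0.55, -0.16 and -0.02. The replication-dependent histone genes had a median of -0.08 and 2 of 23 above 0 (adjusted p = 0.0278, and adjusted p = 0.566 with an estimated correlation), and this call was lost without siScramble array 2 (0.0614), siAirn-001.1 array 2 (0.0777) or siAirn-001.1 array 3 (0.11), and with the lowest genes by level left out (0.126). Cardiac transcription factors missed the threshold by camera (adjusted p = 0.0504), though 5 of 27 rose, including Hopx (0.85) and Mef2d (0.70), with 10 higher and 1 lower adjusted over the list alone. No list was called by camera with an estimated correlation (4 at unadjusted p under 0.05), fry called 5 and the exact permutation of array means 11, without sarcomere (adjusted p = 0.0508) and ribosome biogenesis genes (0.105). The permutation also called 4 lists that camera did not: the Airn locus (only with Airn among its members), IGF2BP and target genes, cardiac transcription factors (higher, 0.0218) and TGF-beta response genes (lower, 0.0218, and 0.0698 by camera).

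In arrays labelled siAirn-001.2, of which 1 had Airn inside the siScramble range, fewer genes passed. Itih4 rose by 1.22 ± 0.25 (adjusted p = 0.0318), Shmt2 by 0.80 ± 0.10 (adjusted p = 0.00121), Pex11a, a peroxisome division gene, by 0.76 ± 0.15 (adjusted p = 0.0278), Mrpl21 by 0.70 (adjusted p = 0.00279) and Spin4 by 0.69 ± 0.09 (adjusted p = 0.00293). Fmod fell by 0.90 ± 0.15 (adjusted p = 0.0125), Itga8 by 0.86 ± 0.14 (adjusted p = 0.00892), and Sytl2, a vesicle transport gene, by 0.85 ± 0.08 (adjusted p = 0.000142). The integrin subunit gene Itgb3 fell by 0.84 ± 0.16 (adjusted p = 0.0217) and Ncs1 by 0.79 ± 0.14 (adjusted p = 0.0155). By the rule that chose them, all 4 arrays lay on the same side of the siScramble mean for each gene. In total 192 genes passed, 97 higher and 95 lower, 30 of them at least 1.5-fold, against 240 and 323 with the replicate block and 387 and 582 with array weights. Without siScramble arrays 1 to 4 in turn the count was 90, 76, 115 and 80, and without siAirn-001.2 arrays 3 and 4 it was 46 and 62. Of the 10 named genes 6 passed whichever array was left out, while Itih4 was lost in 8 fits (adjusted p up to 0.0832), Itgb3 in 6 (0.0899), Pex11a in 5 (0.116) and Ncs1 without siAirn-001.2 array 3 (0.0526).

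With siAirn-001.2, oxidative phosphorylation genes had a median of 0.13 with 61 of 67 above 0 (adjusted p = 3.16e-16, and adjusted p = 0.331 with an estimated correlation). Of these, Uqcrfs1 (0.43), Cox6b1 (0.40), Ndufb8 (0.39), Atp5k (0.33) and Cox5b (0.30) rose, 16 adjusted over the list alone. Fatty acid oxidation had a median of 0.11, with Ucp2 (0.43) higher, and 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.000302). Interferon genes had a median of 0.08 and 32 of 48 above 0, with 2 higher adjusted over the list alone (adjusted p = 0.00104, and 0.0557 without siAirn-001.2 array 4). Ribosome biogenesis had a median of -0.21 with 3 of 46 above 0 (adjusted p = 6.59e-09), and cholesterol biosynthesis a median of -0.18, with 4 of 26 lower and 1 higher adjusted over the list alone (adjusted p = 5.74e-05). With an estimated correlation the adjusted p was 0.792 for these 4 lists. The arrays differed in 2 of them: in siAirn-001.2 arrays 1 to 4 the list means were -0.35, -0.39, -0.04 and -0.01 for ribosome biogenesis (siScramble -0.23 to 0.13) and 0.00, 0.02, -0.35 and -0.28 for cholesterol biosynthesis. Extracellular matrix genes had a median of -0.07 and Fbn2 fell (-0.58), also adjusted over the list alone (adjusted p = 0.0281, and adjusted p = 0.792 with an estimated correlation).

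The other lower lists with siAirn-001.2 were sarcomere genes (median -0.10, adjusted p = 0.0285), DNA replication genes (-0.04, adjusted p = 0.039) and glycolysis and hypoxia genes (-0.04, adjusted p = 0.0225), with an adjusted p of 0.792, 0.792 and 0.793 with an estimated correlation. In the last of these P4ha1, a collagen-modifying enzyme gene, fell (-0.25), with 1 higher and 3 lower adjusted over the list alone. The sarcomere call was lost without siScramble arrays 1 to 4 (adjusted p = 0.103, 0.0661, 0.099 and 0.0839) and without siAirn-001.2 arrays 3 and 4 (0.124 and 0.173). The matrix call was lost without siScramble array 4 (0.0839) and siAirn-001.2 arrays 1 and 4 (0.0593 and 0.095), and the glycolysis call without siAirn-001.2 arrays 3 and 4 (0.39 and 0.173). DNA replication was lost without siScramble arrays 1, 2 and 5 (0.1, 0.0922 and 0.116) and siAirn-001.2 arrays 1 to 3 (0.0565, 0.0926 and 0.124). Other settings also ended calls: the array SD as a covariate for sarcomere (0.0754) and DNA replication (0.119), the fit of these groups alone (0.0555) and repeated quantile normalisation (0.122) for DNA replication, and leaving out the lowest genes by level for DNA replication (0.0933) and glycolysis (0.0719). No list was called by camera with an estimated correlation (2 at unadjusted p under 0.05) or by exact permutation (7 at unadjusted p under 0.05), and fry called 1.

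Both reagents called 125 genes in the same direction, 73 higher and 52 lower, among them Itih4, Kcnj3, Shisa6, Mrpl21, Shmt2 and S100a1 on the higher side and Itga8, Prelp, Fmod, Matn3, Adra2b, Ncs1, Sytl2 and Fbn2 on the lower. None was called in opposite directions by limma, where at an unadjusted p under 0.05 there were 42 such genes and 1084 in the same direction. Independent lists of these sizes would share 3.33 higher and 2.40 lower genes, and no reassignment of residuals gave a shared call. The reassignments do not keep the correlated same-numbered arrays of the reagents together. With the siScramble arrays split so that each reagent had its own 3, the shared calls had a median of 3 and ranged from 0 to 28. The log2 changes of both reagents correlated across genes at r = 0.458, where genes are not independent replicates and reassigned residuals gave a median of 0.401 and a range of -0.355 to 0.843. With split controls r lay between 0.134 and 0.391. The covariance was 0.0113 against 0.00515 in the reassignments, a difference of 0.00615. The shared count was 64, 56 and 57 without siScramble arrays 1, 2 and 4, and 40 and 52 without siAirn-001.2 arrays 3 and 4.

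**Figure D4:**
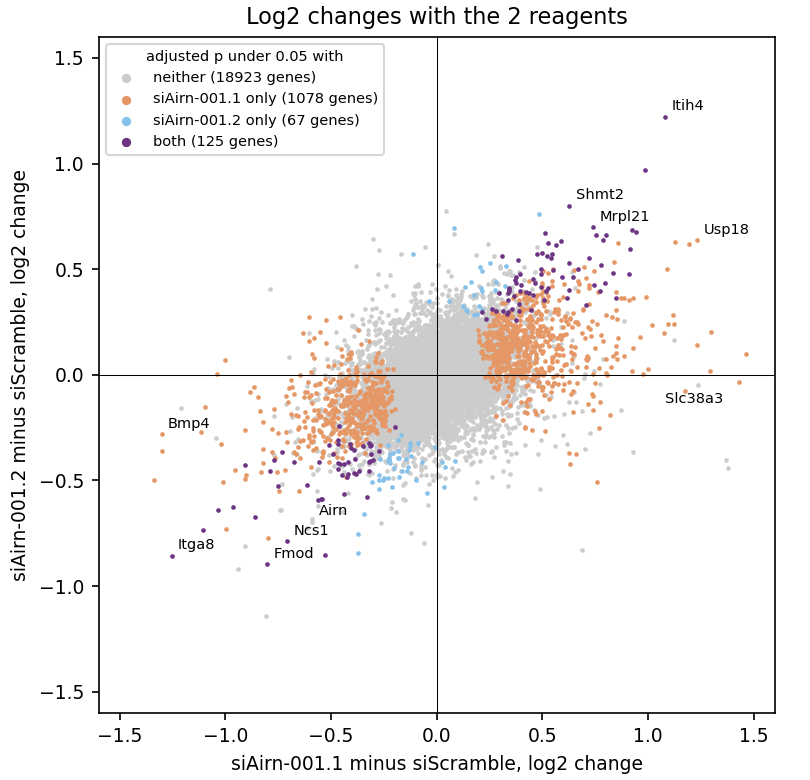
Log2 change of each gene against siScramble with siAirn-001.1 (horizontal) and siAirn-001.2 (vertical), coloured by the contrasts in which limma's adjusted p was under 0.05. The 125 genes called with both changed the same way with each.

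Between the reagents, the largest differences included genes of a transporter, a muscle ubiquitin ligase and signalling proteins. Lower with siAirn-001.2 than with siAirn-001.1 were Slc38a3 (log2 difference -1.47 ± 0.29), Gfpt2 (-1.28 ± 0.19), Zcchc5, now named Rtl3 (-1.27 ± 0.20), Fbxo32, that ligase gene (-1.25 ± 0.23), and Hsd3b1 (-1.09 ± 0.19). Higher were F3, the gene of tissue factor (1.07 ± 0.18), Bmp4 (1.02 ± 0.15), the integrin gene Itga4 (0.95 ± 0.21), Ugdh, which makes a precursor of matrix glycans (0.94 ± 0.13), and the chemokine gene Cx3cl1 (0.90 ± 0.19). By the rule that chose these genes, the 4 arrays of one reagent did not overlap the 4 of the other. The adjusted p ranged from 0.00495 for Ugdh to 0.0412 for Itga4. Within siAirn-001.2, Slc38a3 lay above the siScramble range (9.70 to 10.14) in arrays 1 and 2 (10.64 and 10.62). It lay below that range in arrays 3 and 4 (8.99 and 9.15). Gfpt2 and Fbxo32 were divided in the same way, and the other genes named here were not. In total 203 genes passed, 67 higher and 136 lower, with a split of 117 and 139 under repeated quantile normalisation and 45 and 171 with arrays centred on their median. The count was 132 without siScramble array 1, 82 and 37 without siAirn-001.1 arrays 3 and 4, and 429, 571, 20 and 24 without siAirn-001.2 arrays 1 to 4, and a fit of these 8 arrays alone gave 25. None of the 10 named genes was among those 25 (adjusted p 0.0714 for Ugdh to 0.215 for Itga4). In the fit with siScramble, Bmp4, Ugdh, Gfpt2 and Zcchc5 passed whichever array was left out. Itga4 was lost in 10 fits (adjusted p up to 0.182), Cx3cl1 in 9 (0.145), Slc38a3 in 4 (0.0941), and F3, Fbxo32 and Hsd3b1 in 3 each (0.0681, 0.0892 and 0.0639).

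Of the gene lists, 8 were lower and 4 higher with siAirn-001.2 than with siAirn-001.1. In the sarcomere list Csrp3 (-1.05), Mylk3 (-0.64), Tnni1 (-0.61) and Ldb3 (-0.52) were among the lower genes, with 11 of 28 lower adjusted over the list alone. In the calcium and ion channel list Gja5 (-0.62), a gap junction gene, and Cacnb2 (-0.40) were lower, or 10 of 34 adjusted over the list alone. Its means in arrays 1 to 4 were 0.25, 0.23, 0.10 and 0.19 with siAirn-001.1 and 0.11, 0.07, -0.24 and -0.24 with siAirn-001.2. Cardiac transcription factors had Hopx (-0.74), Hey1 (-0.71) and Mef2d (-0.67) lower, or 6 of 27 adjusted over the list alone. The interferon list had Trim30a (-0.91), Samd9l (-0.79), Gbp2 (-0.56) and Tlr3 (-0.47) lower, or 10 of 48 adjusted over the list alone. Cholesterol biosynthesis had Cyp51 (-0.55) lower, or 6 of 26 adjusted over the list alone, and p53 targets had Plk3 (0.43) higher, or 9 of 31 adjusted over the list alone. For these 6 lists the adjusted p in the order given was 7.12e-10, 3.09e-09, 0.000613, 3.05e-08, 3.08e-08 and 9.58e-08, and the adjusted p was 0.272 with an estimated correlation.

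Another 6 lists differed between the reagents. DNA replication, lipogenesis and glycolysis were lower, each with 2 members adjusted over the list alone (adjusted p = 0.0036, 0.00274 and 5.69e-06). Glycolysis means in siAirn-001.2 arrays 1 to 4 were 0.07, 0.15, -0.38 and -0.30. The adjusted p of these was 0.272, 0.326 and 0.326 with an estimated correlation. NF-kappaB genes, with Cx3cl1 higher, histone genes and ribosome biogenesis genes were higher, with 1, 1 and 0 members adjusted over the list alone (adjusted p = 0.0143, 0.0036 and 0.0139). The adjusted p of these was 0.357, 0.326 and 0.787 with an estimated correlation. The NF-kappaB call was lost without siAirn-001.1 array 1 (0.0817) or siAirn-001.2 array 4 (0.0616), DNA replication without siAirn-001.1 array 1 (0.058), and the histone call without siAirn-001.2 array 1 (0.146). The ribosome biogenesis call was lost without siAirn-001.1 arrays 1 and 2 (0.271 and 0.942) and siAirn-001.2 arrays 3 and 4 (0.184 and 0.523). No list was called by camera with an estimated correlation (3 at unadjusted p under 0.05) or by exact permutation (2 at unadjusted p under 0.05, with 0.0286 the smallest p that 35 splits allow), and fry called 1.

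The other lists were not called for the mean of both reagents, though single members were. In the integrated stress and unfolded protein response, 5 of 33 rose, Nupr1 (0.90), Shmt2 (0.71), Herpud1 (0.37), Mthfd2 (0.36) and Phgdh (0.22), with 7 higher and 2 lower adjusted over the list alone (adjusted p = 0.53). Among immediate early genes Arc (0.61), Ier3 (0.36) and Dusp5 (0.29) rose and Dusp4 (-0.44) fell, with 4 and 1 adjusted over the list alone (adjusted p = 0.256). In the TGF-beta list Tgfb1 rose (0.53) and Tgfb2 fell (-0.92), the same numbers as adjusted over the list alone (adjusted p = 0.186). Apoptosis regulators had Casp2 lower (-0.29), with 3 lower adjusted over the list alone (adjusted p = 0.585), and the RNA interference machinery had Tnrc6b higher (0.37) and Rnasen, now named Drosha, lower (-0.27), with 2 and 2 adjusted over the list alone (adjusted p = 0.996). Oxidative stress genes had Srxn1 higher (0.23) and Gsta3 lower (-0.24), 1 and 1 adjusted over the list alone (adjusted p = 0.653). Cytosolic ribosomal proteins had Rplp1 higher (0.32), also adjusted over the list alone (list adjusted p = 0.489). Cdc25b among mitotic genes (0.31, list adjusted p = 0.918), Hspb7 among cardiac stress genes (0.29, list adjusted p = 0.996) and Rela among NF-kappaB genes (0.41, list adjusted p = 0.996) each rose as the 1 member, also adjusted over the list alone. The heat shock list had no called member by limma, with 5 of 13 at an unadjusted p under 0.05 (list adjusted p = 0.218). Of the 45 list members that the rule selects for this contrast, 21 passed whichever array was left out. Of those named here, Tgfb1, Rplp1 and Gsta3 were lost in 8 of 14 fits each (adjusted p up to 0.123, 0.112 and 0.0905). Rnasen was lost in 7 (0.0983), Tgfb2 in 5 (0.0766), Srxn1 in 2 (0.0572) and Casp2 in 1 (0.0508). In siAirn-001.2 arrays 3 and 4, Tgfb1 (8.53 and 8.40) and Tgfb2 (10.13 and 10.06) lay inside the siScramble range. Median, mean and test differed in sign for 4, 8, 4 and 2 of the uncalled lists in the contrasts of siAirn-001.1, siAirn-001.2, their mean and their difference, and for no called list.

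Markers of other cell types gave no called list in any contrast. For the mean of both reagents the adjusted p was 0.256 for fibroblast, 0.489 for endothelial, 0.296 for smooth muscle and 0.559 for leukocyte markers. Pdgfrb, a receptor gene of mesenchymal cells, fell (-0.34, adjusted p = 0.0333) and Kdr, a VEGF receptor gene, rose (0.39, adjusted p = 0.0336). With 1 array left out, Pdgfrb was lost in 7 of 14 fits (adjusted p up to 0.0886) and Kdr in 8 (up to 0.0744). Both were lost in the fit of the 8 siAirn arrays as 1 group. Kdr was lower with siAirn-001.2 than with siAirn-001.1 (log2 difference -0.64, adjusted p = 0.0273). Beside the interferon and sarcomere lists, the median change of leukocyte markers was -0.02 with siAirn-001.1 and that of smooth muscle markers -0.11 with siAirn-001.2. Of the markers, 5 of 16 fibroblast, 4 of 16 endothelial, 8 of 10 smooth muscle and 1 of 16 leukocyte genes lay above the siScramble median of all genes, 7.49. The highest were Ddr2 (11.56), Egfl7 (8.68), Acta2 (13.98) and Cd68 (7.50), and 6 fibroblast and 2 smooth muscle markers also stand in another list. Which of these markers HL-1 cells express themselves was not tested, so their levels do not show that other cells were present.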

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

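The tests of leukocyte markers and of other cell types were chosen after the results were seen, as was the fit with each array's SD as a covariate.

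Airn was lower in only some arrays of the siAirn groups, and inside the siScramble range in 3 of them. If those 3 were control arrays under a wrong label, the genes called from the other arrays would not shift in them. With each array held out in turn, their lowest shift was 0.79 of the full siAirn shift, against -0.128 to 0.342 in held-out siScramble arrays. Each time the other 2 stayed in the siAirn group and helped to choose the genes. The shift therefore argues only against a wrong label in 1 of them alone, on an array like the siScramble arrays. It cannot decide for all 3 at once, or for control arrays handled together with the siAirn arrays. The shift was not larger where Airn was lowest, at 1.02 and 0.977 in siAirn-001.1 arrays 3 and 4 against 1.16 and 1.16 in arrays 1 and 2, and at 0.474 and 0.554 against 0.79 and 0.864 with siAirn-001.2. An array-wide shift at the level of Airn is also argued against, since the 200 genes nearest to it in level moved by a median of at most 0.0612 in the 4 arrays with the lowest Airn. How well Airn was depleted in each culture, the time of harvest and a shared day of arrays with the same number stay open, and no biological explanation was tested.

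Interferon genes were higher with siAirn-001.1 than with siAirn-001.2 (median difference -0.20, adjusted p = 3.05e-08, and adjusted p = 0.272 with an estimated correlation). RNA from leukocytes would bring its own markers, whose median change with siAirn-001.1 was -0.018, with Cd68 at -0.10 and Fcgr3 at -0.01. With the SD of each array as a covariate the median difference was -0.19. The array SDs were alike in the reagents, 2.09 to 2.19 with siAirn-001.1 and 2.10 to 2.16 with siAirn-001.2. This fit could therefore change the difference little, and no conclusion is drawn from it. All 4 siAirn-001.1 arrays had a list median above the highest siScramble array, and by medians arrays 1 and 2 (0.195 and 0.153) also lay above every siAirn-001.2 array (highest 0.110), but by list means (0.17 and 0.17) they lay below siAirn-001.2 array 4 (0.19), so that a difference carried by arrays 3 and 4 stays open. A response to the siRNA duplex itself and a response to its target may both give this pattern and cannot be separated by this design.

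Sarcomere genes were lower with siAirn-001.2 than with siAirn-001.1 (median difference -0.27, adjusted p = 7.12e-10, and adjusted p = 0.272 with an estimated correlation). A larger share of other cell types would raise their markers, but the highest median difference among 4 such lists was 0.0518. HL-1 cells may express some of these markers themselves, which limits this test. The median difference was -0.264 with the SD of each array as a covariate, which could change it little, since the array SDs were alike in the reagents. The list medians of the 4 siAirn-001.2 arrays spanned 0.127 and all lay below those of siAirn-001.1, though by list means arrays 3 and 4 (-0.22 and -0.23) were lower than arrays 1 and 2 (-0.03 and -0.02). A difference between the reagents in their effect on muscle genes stays open as a hypothesis.

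The counts of genes were set against other splits of the arrays into groups of the same sizes. For siAirn-001.1, 1 of 100 splits reached the real 1203, with 0 as the highest other, and for siAirn-001.2, 2 of 100 reached 192, with 367 as the highest other. For the mean, 1 of 100 reached 833, with 718 as the highest other. For genes called with both reagents, 1 of 100 reached 125, with 0 as the highest other. A share under 0.05 of the splits thus reached each of these 4 counts. The splits treat the arrays as exchangeable, which the correlated same-numbered arrays of the reagents go against. They therefore do not exclude a structure of the samples as a source of these counts. For the difference between the reagents, 2 of 35 splits reached 203 in the fit without a block, and chance cannot be excluded there. The highest other split gave 1677 genes and set arrays 3 and 4 of both reagents against arrays 1 and 2, which points to a structure of the samples. That split parts none of the 4 same-numbered pairs of the reagents, whereas the real split parts all 4. Of the other splits, 24 part 2 pairs and gave at most 1 gene, and 7 part all 4 and gave 0. With the replicate number as a block, 1 of 35 splits reached the real 293, with 27 as the highest other. Only the 8 splits that part all 4 pairs are like the real one in that fit, and 8 are too few for a share under 0.05. Chance cannot be excluded for the numbers of called lists either. For the difference, 12 of 35 splits gave at least the real 12, with 17 as the highest other. For siAirn-001.1, 36 of 100 splits gave at least the real 9, with 17 as the highest other, and for siAirn-001.2, 44 of 100 gave at least 9, with 18 as the highest other. For the mean, 67 of 100 gave at least 6, with 17 as the highest other.

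In 6 cases 1 array lay far from the others of its group for a named gene. Mrpl21 was at 7.91 in siScramble array 4 (others 8.27 to 8.36), Adra2b at 8.75 in siScramble array 1 (others 9 to 9.13), F3 at 9.88 in siScramble array 1 (others 10.11 to 10.18) and Polk at 9.43 in siScramble array 3 (others 9.81 to 10.00). Srxn1 was at 9.53 in siAirn-001.1 array 4 (others 9.37 to 9.39) and Tnrc6b at 10.09 in siAirn-001.2 array 1 (others 9.79 to 9.84). Chance gives such a case in about 1 of 20 groups, or 12.2 of the 243 groups tested.

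Differences between the reagents, as siAirn-001.2 minus siAirn-001.1, passed limma's test for several named genes. The log2 difference was -1.47 for Slc38a3, -1.09 for Hsd3b1, -1.28 for Gfpt2, -1.27 for Zcchc5, -1.25 for Fbxo32, -0.52 for Ldb3, -0.74 for Hopx and -0.64 for Kdr. It was 1.02 for Bmp4, 0.94 for Pak3, 0.61 for Spin4, 1.07 for F3, 0.95 for Itga4, 0.94 for Ugdh and 0.90 for Cx3cl1. Gene lists whose camera test passed for this difference had medians of -0.26 for calcium and ion channel genes, -0.10 for cardiac transcription factors, 0.23 for p53 targets, 0.064 for NF-kappaB genes, -0.059 for DNA replication, 0.076 for histones, -0.16 for cholesterol biosynthesis, -0.14 for lipogenesis, -0.10 for glycolysis and hypoxia and 0.10 for ribosome biogenesis, besides the interferon and sarcomere lists. With an estimated correlation none of the 12 passed, and 3 lists had an unadjusted p under 0.05. By fry 1 passed.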

How the results depend on the processing

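The fits with each array's SD as a covariate, without siScramble arrays 5 and 6 and with pairs of replicate numbers as a block, the exact permutation of list means, and that permutation without Airn in its locus list, were chosen after the data were seen. No gene or list result called in the main fit or in an alternative changed sign between the 2 fits. Sign changes of results called in neither fit were not counted. The balance of higher and lower genes did turn in some settings, as given above. Of 94 results for named genes, 46 stayed on the same side of the adjusted p of 0.05 under every alternative run for them, which leaves out the 1.5-fold and 0.01 thresholds, applied to counts only. Of 36 list calls 0 did, since camera with an estimated correlation ended all 36. Leaving out 1 array ended a gene call 191 times and a list call 31 times over all 14 fits. The number of arrays, and signal over background for dim genes, limit what could be detected. The alternatives with several probe sets per gene were not run because no gene has a second one.

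Counts are given for siAirn-001.1, siAirn-001.2, the mean, the difference and genes shared in direction. With the replicate number as a block they were 1845, 563, 1550, 293 and 375. For the difference, where the numbers pair the reagents, the block called the same 12 lists and the same 10 named genes. None of those 10 genes passed in the fit of only the 2 reagents, while no list call of the difference was lost there. The numbers did not pair siScramble with the siAirn groups: 4 of 8 same-numbered pairs had deviations correlated above 0.1 (range -0.429 to 0.234). Of 12 arrays numbered 1 to 4, 8 correlated best with their own number in another group. With pairs of numbers as a block, which divides the siAirn arrays as the Airn level does, they were 2310, 940, 1956, 676 and 585. In both block fits siScramble arrays 5 and 6 have block levels of their own, so changes against siScramble rest on its arrays 1 to 4. The median change over all genes was thus the same as without siScramble arrays 5 and 6 (0.00925 for the mean). Array weights gave 1906, 969, 1927, 509 and 376. Fits of only the groups compared gave 548 for the mean and 25 for the difference. Repeated quantile normalisation gave 300 for siAirn-001.2. With the SD as a covariate siAirn-001.2 had 295 and the shared count was 188, and without siScramble arrays 5 and 6 these were 413 and 260. A 1.5-fold minimum left 241, 30, 71, 86 and 18, and an adjusted p under 0.01 left 446, 26, 234, 21 and 21. For these the stricter threshold is the cause, for the others the cause was not tested.

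Called lists for siAirn-001.1, siAirn-001.2, the mean and the difference numbered 0, 0, 0 and 0 by camera with an estimated correlation (4, 2, 3 and 3 at unadjusted p under 0.05), 5, 1, 3 and 1 by fry, and 11, 0, 0 and 0 by exact permutation of list means. The Airn change with siAirn-001.1, siAirn-001.2 and their mean was -0.56, -0.66 and -0.61 with the replicate block (adjusted p = 0.0405, 0.0418 and 0.0169) and the same with pairs of numbers as a block (0.0209, 0.0181 and 0.00652). With array weights it was -0.86 for siAirn-001.2 (0.0208) and -0.68 for the mean (0.0152).

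Leaving out each array in turn gave 770 to 1259 genes for siAirn-001.1, 46 to 254 for siAirn-001.2, 378 to 981 for the mean, 20 to 571 for the difference and 40 to 155 shared. The correlation ranged from 0.299 to 0.574. Called lists ranged from 9 to 13, 7 to 12, 5 to 9 and 9 to 15 in the 4 contrasts. The Airn change ranged from -0.75 to -0.44 with siAirn-001.1 (adjusted p 0.0934 to 0.398), -0.91 to -0.50 with siAirn-001.2 (0.0726 to 0.543) and -0.75 to -0.55 for the mean (0.0315 to 0.165). Arrays whose absence moved a count by over 1.5 times are named beside each count above.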

Other observations

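The gene families here and their tests were chosen after the results were seen.

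Mitochondrial carrier genes, the Slc25a family that moves metabolites across the inner membrane, had a median log2 change of 0.04 over 44 genes for the mean of both reagents, with 29 above 0 (camera adjusted p = 0.00782 over 5 families, and adjusted p = 0.0452 with an estimated correlation). With siAirn-001.2 their median was 0.07 (adjusted p = 0.00502, and adjusted p = 0.0361 with an estimated correlation), and with siAirn-001.1 it was 0.00 (adjusted p = 0.0694). Proton pump subunits (21 genes, adjusted p = 0.0838), proteasome subunits (39 genes, 0.223) and zinc finger genes (317 genes, 0.069) were not called for the mean. Zinc finger genes passed with siAirn-001.2 (median 0.03, camera adjusted p = 0.0464, and adjusted p = 0.714 with an estimated correlation).

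Because Mrpl21 was among the largest rises, the hypothesis that mitochondrial ribosomal protein genes moved together was tested. Their median was 0.0107 over 71 genes for the mean (adjusted p = 0.182), with 4 of them higher by limma, so the test gave no sign of a shared move.

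In 329 genes all 8 siAirn values lay outside the 6 siScramble values on one side, 180 of them higher. These are 1.63% of genes, where the average over all splits of these sizes is 0.0666%. Genes are correlated, so a single split can lie well above that average without an effect of the siRNAs. Other splits were not counted for this measure.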
